A study of Homo sapiens with 6 samples.

How the data were processed

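Ribosome-protected fragments were sequenced from CHL-1, an established human melanoma cell line, in 6 libraries that fall into 3 groups of 2. The groups are a line edited with CRISPR at SNORD50A/B, a pair of box C/D small nucleolar RNA genes, the untreated parental line, and cells given 10 mM AZC (azetidine-2-carboxylic acid, a proline analog) with 20 µM MG132 (a proteasome inhibitor) for 20 minutes. In each group 1 library carries the label that ribosomal RNA was removed and the other does not. Per the labels' protocols, cells were lysed in a buffer with cycloheximide, which holds ribosomes on the messenger, and libraries followed a published ribosome profiling protocol. The submitters' processing notes name Bowtie2 and TopHat2, without versions, and the genome build hg19. How both libraries of a group entered a table is not given in the sources used here.

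The deposited values are 3 tables, 1 per condition, each with 400 bins per RefSeq transcript, and they are on a log2 scale: each is log2(x + 1), rounded by the authors to 2 decimals, where x is a whole number read here as the summed read depth of the bases in the bin. Bins 1 to 100 cover the 5′ UTR, bins 101 to 300 the coding sequence and bins 301 to 400 the 3′ UTR, a reading taken from the values. The last 3 rows of each table hold summaries over transcripts, labelled median, median_norm and Ave, and were left out of the gene values. No sample has a column of its own, so no spread between replicates exists in these tables and no p-value is given. Depth counts bases, not reads, so no counting interval was computed and the number of distinct fragments is unknown.

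In the coding bins the deposited log2 values also contained the deposited value of the row above, added to x before the logarithm. After the row above was subtracted, 100% of the low coding bins (log2 under 4) were whole numbers within the rounding error in each of the 3 tables. With a random row subtracted the share was 6.65% in the parental table, 5.97% in the CRISPR table and 6.42% in the AZC + MG132 table. No bin became negative beyond the rounding error. UTR bins were whole as deposited. The carried part made up 4.37%, 3.42% and 5.31% of the coding depth in the parental, CRISPR and AZC + MG132 tables, and all values below were computed after it was removed.

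Transcripts listed numbered 19302 in the parental, 19783 in the CRISPR and 18409 in the AZC + MG132 table. Gene names came from the RefSeq gene table of assembly GRCh38.p14, used for names only, which left 219, 237 and 211 transcripts without a name. Those unnamed rows held 3.93%, 3.11% and 6.02% of the depth. They stayed in the totals and out of the gene comparisons. How the listed transcripts were selected is not given in the sources used here.

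The level of a gene is its normalised depth, which is the depth summed over its 400 bins, divided by the table's total and multiplied by 1000000, from the transcript with the highest mean level over the 3 tables. A log2 ratio used a pseudocount of 0.5 on the summed depth. A gene was compared where its depth was above the lower quartile of row sums in both tables, which is 3187 in the parental, 3697 in the CRISPR and 2614 in the AZC + MG132 table. Genes with a log2 ratio of 1 or more in size are called past 2-fold below, a limit of size and not a test. The 5′ share of a gene is the mean depth of the first 20 of its 200 coding bins over the mean of all 200, and a 5′ shift is the log2 ratio of the 5′ shares of 2 tables, over the 7075 genes above the minimum in all 3 tables. Ratios were also taken from the first 100 and from the last 100 coding bins. The average profile is the mean over all rows of log2(x + 1) per bin, divided by its mean over the 400 bins.

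For each of 22 gene lists fixed before the data were examined, the median log2 ratio was placed among 10000 random lists of the same size matched on mean level in 10 level bins. These percentiles describe the tables and are not tests between conditions. Genes named below are, per comparison, the 10 with the largest rise and the 10 with the largest fall among genes above the median of mean level, then per list the 2 with the largest ratio and the 2 with the highest level, and a fixed set of 10 (among them SNHG5, NRAS, HRAS, FNTA, FNTB, ATF4, HSPA8, ACTB and GAPDH). SNHG5, the host gene of SNORD50A and SNORD50B, had no row in the 3 tables. The edit could not be checked from footprints of messengers, and the label was taken as given. Some genes that the rule names are not reported here. Rows of near-identical genes (HSPA1A and HSPA1B, PABPC1 and PABPC3, ACTB and ACTG1, members of the TRIM48 family and histone copies) can share reads, and their separate values are uncertain.

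The steps were tested on simulated tables for AZC + MG132 against parental, with reads of 30 bases drawn from the parental profile. Each fold was built into 50 genes. Of 7784 genes compared, the simulation called 100% of the 23 genes lowered to 0.25-fold and 100% of the 30 lowered to 0.4-fold. The other lowered genes did not pass the level minimum in both tables and were not compared, so falls below that minimum are missed. The simulation called 98% of the 50 raised 2.5-fold, 100% of the 50 raised 4-fold, and 0 of 7631 unchanged genes. A built-in 5′ shift of 0.51 was recovered as 0.49. The simulation holds counting noise only. Alternatives covered the pseudocount, the level minimum, the scaling, the collapse to 1 row per gene, the 5′ window, the bins used and the carried part; their effect is in the closing section. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.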

Results

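Ribosome footprints of CHL-1 melanoma cells were read from 3 tables, for the parental line, the line edited at SNORD50A/B and parental cells given AZC with MG132. The edit itself could not be checked from these footprints of messengers, and the host gene of SNORD50A and SNORD50B has no row in the 3 tables. Summed depth over all bins, in units of 1000000, was 473.7 in the parental, 586.5 in the CRISPR and 367.3 in the AZC + MG132 table. Coding bins held 85.6%, 84.8% and 78.1% of it. The share in 5′ UTR bins was 10.0% in the parental, 10.7% in the CRISPR and 15.7% in the AZC + MG132 table. Each condition has 1 table and no replicate, so every difference below is between single tables, without a test. Levels are normalised depth.

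The treated cells were compared with the parental table to see which messengers ribosomes occupied after a short proteotoxic stress. ATF4 (NM_001675), the transcription factor of the integrated stress response, stood at 1048 against 135.2, a log2 ratio of 2.96. DDIT3, a pro-apoptotic factor of the same response, was 8.27-fold higher, and DDIT4, an inhibitor of mTORC1 signalling, was 6.60-fold higher. The DDIT3 value is over all bins, and its 5′ UTR depth was 257.1% of coding depth in the parental and 81.6% in the AZC + MG132 table. GADD45B was 6.28-fold, FOS 5.43-fold and DUSP1 3.85-fold higher. The inducible HSP70 genes HSPA1B and HSPA1A stood at log2 ratios of 1.96 and 1.88, with reads that the pair can share, and their co-chaperone DNAJB1 at 1.63. IFRD1 was at 1.69.

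The lower genes included messengers of the translation machinery. PABPC1, the poly(A)-binding protein, was at 64.3 against 364.3, a log2 ratio of -2.50, and its near copy PABPC3 at -2.82. TPT1 was at -1.69 and RPL12 at -1.67. GIT1 and SCARA3 were both at -1.97, ATP13A3 at -1.66, INTS1 at -1.64 and DNAJC13 at -1.62. Of 7279 genes, 0.866% were 2-fold or more higher in the AZC + MG132 table and 2.39% lower. Of the genes past 2-fold 26.6% were higher, a share of 39.3% when scaled to the median ratio and of 44.7% with the most abundant 1% of rows left out of the total. With a level minimum 4 times higher 1.32% of genes were past 2-fold.

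**Figure D1:**
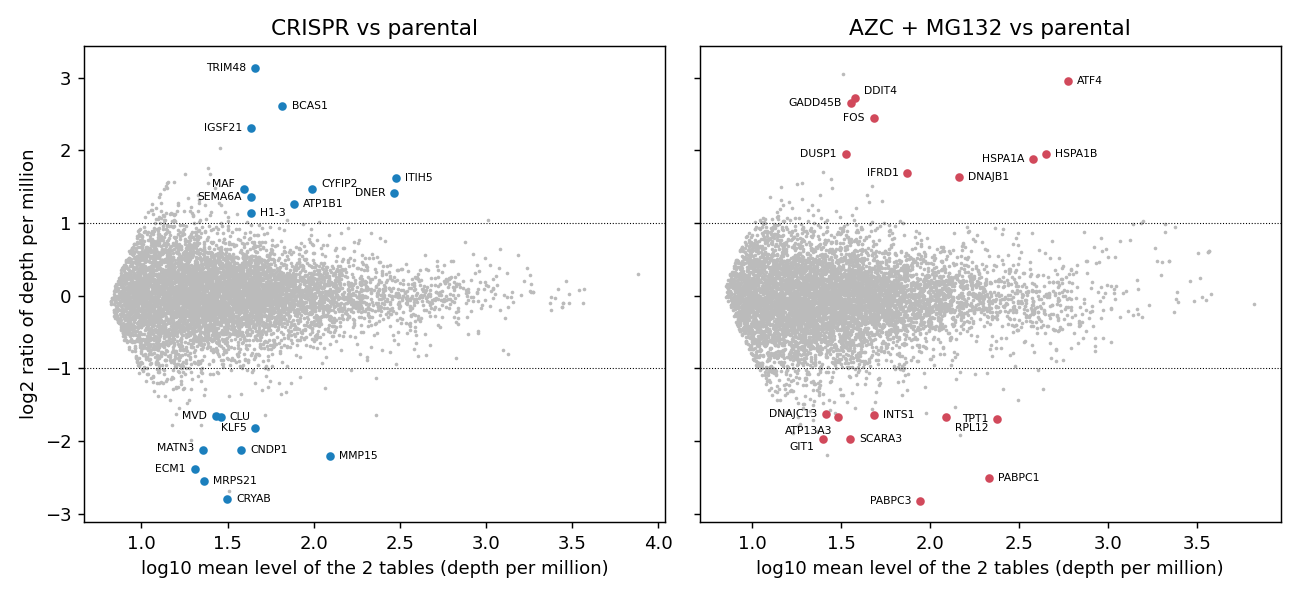
Log2 ratio of normalised depth (vertical axis) against the log10 mean level of the 2 tables (horizontal axis), 1 point per gene, for CRISPR against parental (left) and AZC + MG132 against parental (right). Coloured points are genes of the 10 largest rises and 10 largest falls among genes above the median level that are reported in the text, and dotted lines mark log2 ratios of 1 and -1; ATF4 stands at 2.96 in the treated cells and TRIM48 at 3.14 in the edited line.

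By gene list, the immediate early genes, first transcribed after a stimulus, had a median of 0.71 over 14 members in the treated cells, above all 10000 random lists. Of these, 5 were past 2-fold, all higher (CCN1, DUSP1, FOS, IER2 and KLF10, of which CCN1, IER2 and KLF10 are named after their values were seen), while MYC stood at 0.02 and MCL1 at 0.50. Replication-dependent histones had a median of 0.63 over 32 members, also above all random lists, with H2BC11 at 1.02 and H3C14 at 0.61. Near-identical histone copies can share reads, so the 32 members may not be separate values as the genes of random lists are. The integrated stress response list had a median of 0.25 (percentile 99.6), with 3 of 16 members past 2-fold, ATF4, DDIT3 and DDIT4. The proteasome and ubiquitin list lay at 0.08 (percentile 97.7), with 0 of 44 members past 2-fold and PSME2 at 0.58.

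Ribosomal protein genes had a median of -0.25 over 85 members, below all random lists, with 3 past 2-fold, all lower. These were RPL12, RPLP1 at -1.15 and RPS12, while the abundant RPL3 was at -0.18. Collagen and matrix genes had a median of -0.28 (percentile 1.98), with 0 of 15 past 2-fold; P4HA1, a collagen prolyl hydroxylase subunit, was at -0.79. Among cytosolic chaperones 4 of 31 members were past 2-fold, all higher (HSPA1A, HSPA1B, DNAJB1 and DNAJB4), but the median of the list, -0.05, changed sign with the scaling. The same change of sign held for translation factors (median -0.05, with PABPC1 and TPT1 past 2-fold), ER folding genes (-0.06), ERK pathway output (-0.02), cell cycle (-0.04) and cytoskeleton (-0.05). In the ER list HERPUD1 was at 1.39 and HSPA5, the ER HSP70, at 0.66.

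Other medians lay inside the central 95% of random lists. They were -0.14 for aminoacyl-tRNA synthetases, 0.0045 for oxidative stress, -0.24 for RAS, RAF and prenylation, 0.04 for C/D snoRNP genes, 0.24 for melanocyte lineage, -0.35 for the mesenchymal and invasive state, 0.21 for p53 targets and -0.10 for glycolysis. Among markers of other cell types only KRT10 passed the minimum, at -0.48. Its coding bins held 5.77% of its depth in the parental and 12.6% in the AZC + MG132 table. Coding bins alone were thus higher in the treated cells, so the direction for KRT10 depends on the bins used. No mitochondrially encoded gene was listed. MAP2K2 was at a log2 ratio of -1.09 and NRAS at 0.32. HSPA8 was at 0.58, ACTB at 0.02 and GAPDH at -0.22.

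**Figure D2:**
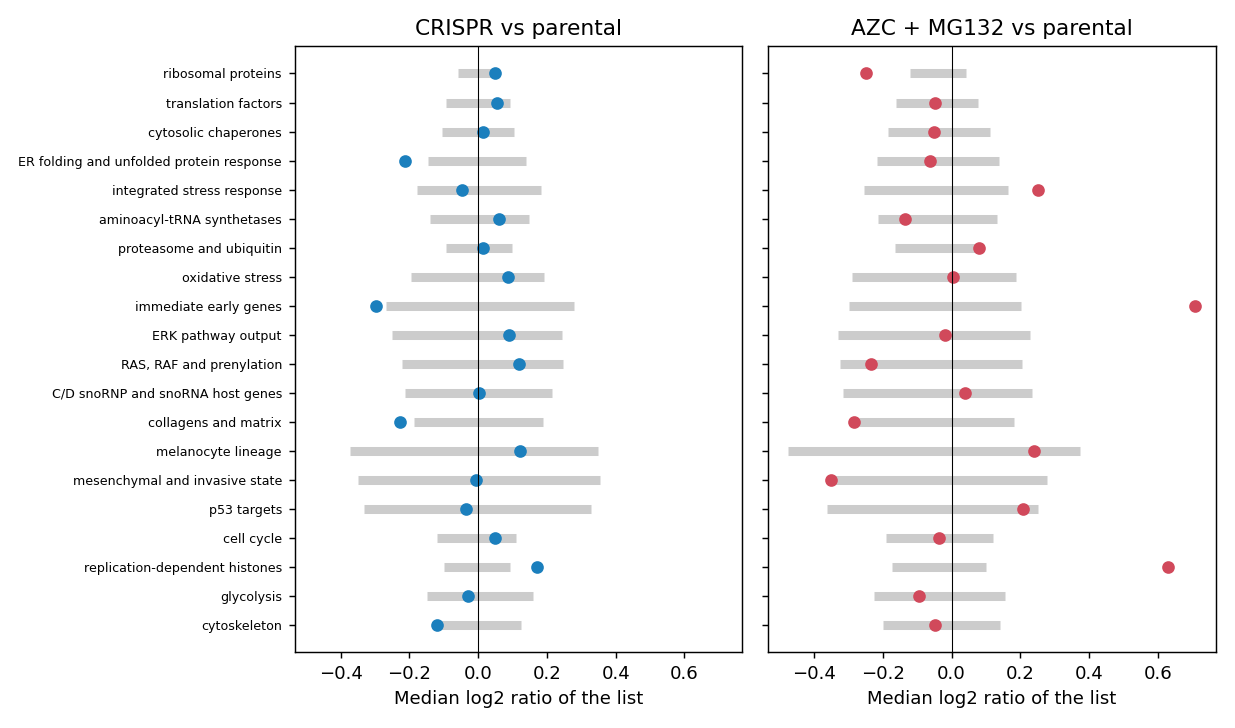
Median log2 ratio of each gene list (points) for CRISPR against parental (left) and AZC + MG132 against parental (right), with grey bars for the central 95% of medians of 10000 random lists matched on level. Immediate early genes (0.71) and histones (0.63) lie above their bars in the treated cells and ribosomal proteins (-0.25) below.

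Along the ATF4 messenger, whose short upstream reading frames begin in the 5′ UTR, the tables differed in where depth lay. In the parental table the 5′ UTR carried a normalised depth of 101.1 and the coding sequence 33.5. In the AZC + MG132 table they carried 332.5 and 692, which puts the coding sequence at 20.6 times the parental level. In the CRISPR table the values were 178.3 and 51.8. Much of the coding depth lay near its start in the parental and CRISPR tables, with 5′ shares of 4.91 and 4.99. In the AZC + MG132 table the 5′ share was 1.41, so the 20.6 is not uniform along the coding sequence. Bins do not tell reading frames apart, so depth near the start cannot be assigned to the ATF4 frame. ATF4 was singled out here after its values were seen.

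**Figure D3:**
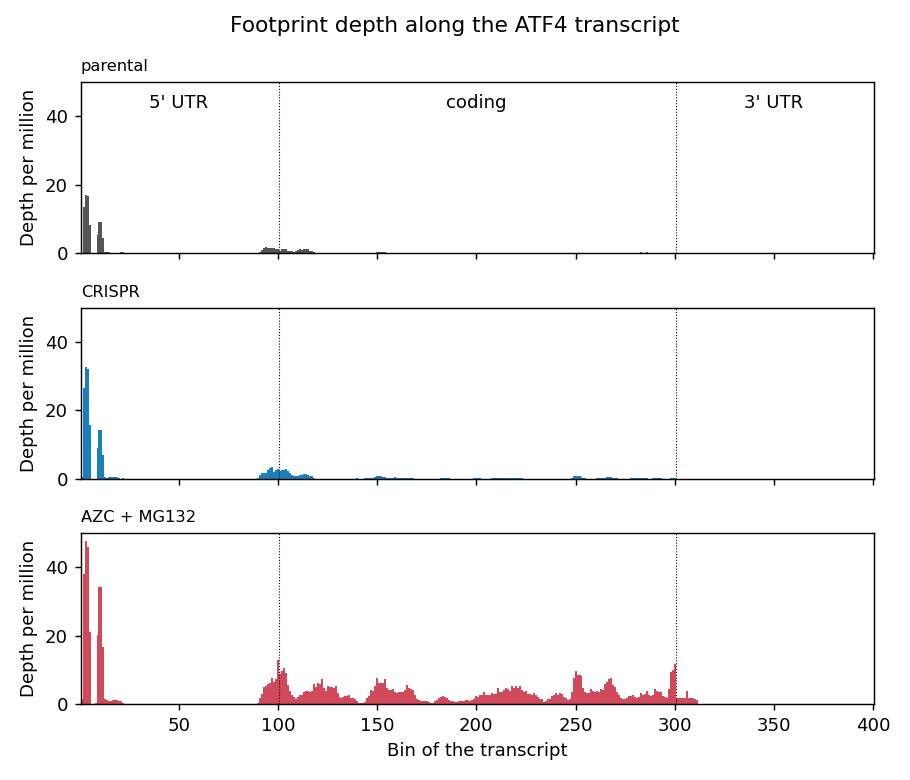
Normalised depth (vertical axis) in each of the 400 bins of the ATF4 transcript (horizontal axis), 1 panel per table, with dotted lines at the ends of the coding sequence. Coding depth sums to 33.5 in the parental, 51.8 in the CRISPR and 692 in the AZC + MG132 table.

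The position of footprints was compared next, since the treatment acts on protein synthesis and quality control. In the AZC + MG132 table the median 5′ share was 1.43 (interquartile range 0.93 to 1.96 over 7075 genes), against 0.93 (0.63 to 1.29) in the parental table. Within genes the 5′ shift had a median of 0.60 on the log2 scale (interquartile range 0.12 to 1.05), and 79.3% of the genes were above 0. Cytosolic chaperones had a median shift of 0.96 (percentile 99.985), with 30 of 31 members above 0. Ribosomal proteins were at 0.75 and RAS, RAF and prenylation genes at 0.30, both inside the random range.

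Along the coding sequence of the treated cells the mean scaled depth was 1.51 in the first 20 bins and lowest, at 0.83, in the 20 bins before the last 20, while the parental table held 1.02 and 0.97 there. In the average profile over all 400 bins, the ratio of AZC + MG132 to parental was 1.24 in the 5′ UTR, 1.10 in the first 20 coding bins, 0.91 in the middle 100, 0.88 in the last 20 and 1.66 in the 3′ UTR. Among windows of 20 bins the highest ratio, 2.89, was at the far end of the 3′ UTR and the lowest, 0.87, in the 20 coding bins before the last 20. The profile averages log2 values, so these ratios are not folds of depth, least so in the 3′ UTR, where values are near 0. The 3′ UTR held 6.15% of summed depth in the AZC + MG132 and 4.38% in the parental table. Per gene, depth in the 5′ UTR was a median of 11.6% of coding depth in the treated cells and 5.88% in the parental line.

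**Figure D4:**
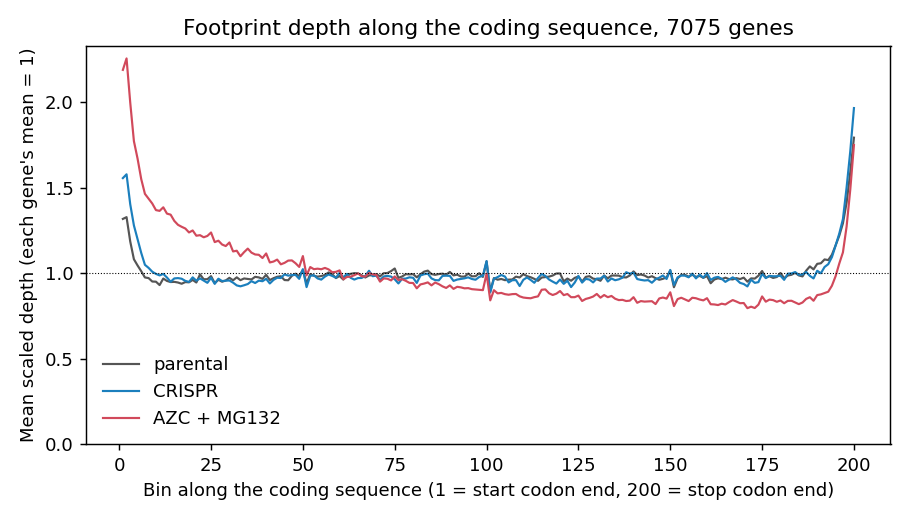
Mean scaled footprint depth (vertical axis, the mean of each gene set to 1) in the 200 bins of the coding sequence (horizontal axis) over 7075 genes, 1 line per table. The AZC + MG132 line averages 1.51 over the first 20 bins and 0.83 over the 20 bins before the last 20.

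The edited line was compared with the parental line to see which messengers differ in footprint depth. No control-edited line is among the groups, so differences between the lines unrelated to the edit can enter too. TRIM48 (NM_024114) was 8.80-fold higher in the CRISPR table, with reads its close relatives can share. BCAS1, known from oligodendrocytes, was 6.10-fold and IGSF21 4.95-fold higher. ITIH5 was at 455 against 148.5, and DNER, a Notch ligand, at 427 against 159.9. MAF stood at a log2 ratio of 1.47, CYFIP2 at 1.46, SEMA6A at 1.35, ATP1B1 at 1.26 and the linker histone H1-3 at 1.14.

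On the lower side, CRYAB, a small heat shock protein, was at 7.89 against 54.96, a log2 ratio of -2.80. MRPS21 was at -2.54, ECM1 at -2.38 and the membrane metalloprotease MMP15 at -2.20. MATN3 was at -2.12, CNDP1 at -2.11, KLF5 at -1.82, the secreted chaperone CLU at -1.66 and MVD, an enzyme of the mevalonate pathway, at -1.65. Of 7543 genes, 83 were 2-fold or more higher and 98 lower. In both the first and the last 100 coding bins, which are part of the sum that selected these genes, 37 of the 83 and 47 of the 98 were past 2-fold. Across all compared genes the ratios from these bins correlated at r = 0.20, and the CRISPR table covered a median of 69% of the coding bins of a gene against 90.5% in the parental table.

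Of the lists, 4 lay outside the central 95% of random lists in this comparison. ER folding genes had a median of -0.21 (percentile 0.26), with 0 of 22 past 2-fold; P4HB was at -0.68, HSPA5 at -0.31 and HSP90B1 at 0.0071. Collagen and matrix genes had a median of -0.23 (percentile 0.95), and COL6A1 at -1.02 was the only 1 of 14 past 2-fold. Immediate early genes had a median of -0.30 over 11 members (percentile 1.75), with DUSP2 at -0.91 and FOS at 0.63. Histones had a median of 0.17 over 32 members (percentile 99.97), with H1-3 past 2-fold and the abundant H3C14 at -0.09. With 60 list percentiles over the 3 comparisons, 3 would lie outside by chance if lists were independent.

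The other medians were 0.05 for ribosomal proteins, 0.06 for translation factors, 0.01 for cytosolic chaperones (DNAJB4 at 1.24, CRYAB at -2.80), -0.05 for the integrated stress response, 0.06 for aminoacyl-tRNA synthetases, 0.01 for the proteasome, 0.09 for oxidative stress, 0.09 for ERK pathway output and 0.12 for RAS, RAF and prenylation genes. They were 0.12 for melanocyte lineage, -0.01 for the mesenchymal state (LOXL2 at -1.54), -0.04 for p53 targets, 0.05 for cell cycle, -0.03 for glycolysis and -0.12 for cytoskeleton. C/D snoRNP genes had a median of 0.0029 whose sign changed with the scaling; NCL was at 0.56 and NOP56 at -0.56. NRAS was at 54.6 against 41.5, with a log2 ratio of -0.17 in the first 100 coding bins, FNTA at 18.6 against 17.4 and FNTB at 28.2 against 23.5. HRAS was above the level minimum in the parental table only. KRT10, the only marker of other cell types above the minimum, was at -0.57, with its depth in 3′ UTR bins for 94.2% in the parental and 100% in the CRISPR table, so its coding bins give no ratio. ACTB was at -0.09, GAPDH at 0.10 and HSPA8 at -0.04. Genes past 2-fold were 2.40% of those compared and 0.835% with a level minimum 4 times higher. Values as deposited, which hold the row above in their coding bins, gave 48 higher and 78 lower. A minimum of 100 covered coding bins in both tables kept 60 of the 83 higher and 39 of the 98 lower genes; a gene lower in the CRISPR table can lose covered bins there, so these counts do not bear on the balance of higher and lower genes.

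The edited line was compared with the parental table by position as well. The median 5′ share was 0.96 (interquartile range 0.56 to 1.46) against 0.93, the median 5′ shift was 0.06 on the log2 scale (-0.51 to 0.54), and 53.6% of genes were above 0. Histones had a median shift of 0.30 and ribosomal proteins of 0.22, at percentiles 99.1 and 98.5. As for the levels, 3 of 60 list percentiles would lie outside by chance if lists were independent. The shift lists outside, these and the cytosolic chaperones of the treated cells, were no more than that in number. That count does not weigh how far out a list lies, and the chaperones were at percentile 99.985. In the average profile the CRISPR to parental ratio was 1.03 in the 5′ UTR, 1.02 in the first 20 coding bins, 0.99 in the middle 100, 1.002 in the last 20 and 1.02 in the 3′ UTR. This profile is a mean over rows; as a median over rows the first 20 coding bins stood at 0.805 times the mean of all bins in the CRISPR table and 1.87 times in the parental table.

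The edited line and the treated cells were set side by side without the parental table. Of 7220 genes, 4.16% were 2-fold or more higher in the CRISPR table and 2.35% lower. Of the genes past 2-fold 63.8% were higher, a share of 54.9% when scaled to the median ratio and of 52.97% without the most abundant 1% of rows in the total. IGSF21 was 9.44-fold, PABPC1 5.50-fold and ODC1, the first enzyme of polyamine synthesis, 4.29-fold higher in the CRISPR table. MRPS21 was at a log2 ratio of -3.03, CRYAB at -2.85, DDIT4 at -2.76, ATF4 at -2.19 and HSPA1A at -2.19. Ribosomal proteins had a median of 0.30, above all random lists, with 6 of 85 past 2-fold. Immediate early genes (-1.09, with 7 of 11 past 2-fold, all lower), histones (-0.43) and the integrated stress response (-0.26, percentile 1.90) lay below their random range. The median 5′ shift was -0.54 (interquartile range -1.15 to 0.0026), with 25.1% of genes above 0.

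Across 7075 genes the changes of the edited line and of the treated cells, both against the shared parental table, correlated at r = 0.23 (Spearman's rho 0.23, covariance 0.0442). Genes are not independent replicates, and the shared table adds to this value. Unchanged tables simulated with counting noise alone gave a covariance of 0.00557 and r = 0.49. When each change was taken from a different set of 100 coding bins, so that each used other parental bins, r was 0.0348. With the same set for both changes it was 0.249. The 2 sets correlated at only 0.20 within the CRISPR and 0.35 within the AZC + MG132 comparison. The fall to 0.0348 therefore cannot be credited to the shared parental bins alone. Past 2-fold in both were 8 genes higher, GADD45B and DNAJB4 among them, where independent lists would give 0.609 and the simulated tables gave 0. There were 4 lower (CORO1A, EIF2AK4, ITGB4 and MMP15), where independent lists would give 2.37 and the simulated tables gave 0. The first value leaves out the shared parental table and the simulation leaves out noise beyond counting, so part of any excess may come from the shared table; genes of both overlaps are named after their values were seen.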

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

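Genes listed in only 1 table of a pair did not enter the comparison of that pair. Of 643 genes listed in the CRISPR table and not in the parental table, 51 were above the level minimum. The highest were PEG3, an imprinted gene, at a normalised depth of 51.6, SYNE1 at 33.03 and CRACR2A at 27.2, none of them listed for the treated cells either. Of the genes listed in the AZC + MG132 table and not in the parental table, 13 were above the minimum, led by CHAC1, a glutathione-degrading enzyme induced by ATF4, at 27.1, SH3TC2 at 20.7 and ADGRV1 at 13.4. ADGRV1 was also listed in the CRISPR table, at 15.1. In the opposite direction, 707 genes were listed in the parental table and not for the treated cells, 75 of them above the minimum, led by MPRIP at 29.7 and ARHGEF12 at 20.5. Of genes listed in the parental table and not in the CRISPR table, 26 were above it. The rule that decided which transcripts a table lists is not given, so no fold is stated.

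In the 3 patterns that follow, the tests on start codon reads, on the share of genes, on the other pair of tables, on total depth and on short coding sequences were chosen after the results were seen. The 5′ shift in the AZC + MG132 table argues against lower depth as the whole cause, since the 10% of genes with the highest level had a median shift of 0.67. Reads at the start codon are not the only difference in position. With the first 20 coding bins left out, the next 40 bins were set over the 40 bins that end at coding bin 180. This stood at a median log2 ratio of 0.45 against parental, and at -0.0045 for CRISPR against parental. It is another ratio than the 5′ shift and does not give the part of the shift from reads near the start. With only the first coding bin left out the shift was 0.59. A few abundant genes could not produce the 5′ shift, since each gene counts once in the median. With a lower quartile of 0.12 already known, the 79.3% of genes above 0 added no test. Chance differences between single tables cannot be told apart from the treatment, because no replicate table exists; the only other pair against parental, CRISPR, differed by 0.0591. An effect of the treatment on elongation stays open and untested.

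The CRISPR table covered fewer coding bins although its total depth, 586 in units of 1000000, was the highest, so lower depth is not the cause. In the 10% of genes with the lowest level the coefficient of variation over coding bins was 1.41 times that of the parental table, and in the 10% with the highest level 1.16 times (95% range over 1000 resamplings of genes 1.14 to 1.18). That decline with level is consistent with fewer distinct fragments behind the depth. Ribosomes on fewer positions of every coding sequence were predicted to keep the ratio at 1.2 or more in the highest group, which was not met. That limit was set by choice, so a smaller effect on positions is not excluded. The excess that remains there is unexplained, and an effect of the edit was not tested apart from it.

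Replication-dependent histones were higher in the treated cells. A different division of reads among near-identical copies would leave their sum near the parental one, but the summed depth of the 34 listed histone genes was 1.58 times parental. This argues against such a division only if each read was assigned to 1 copy. H3C14 and H3C15 had near-equal 5′ shares, both 1.439 in the parental and both 2.62 in the AZC + MG132 table. The same reads may therefore be counted in several copies, and the sum cannot decide about shared reads. Signal in UTR bins is not needed, since coding bins alone gave a median log2 ratio of 0.71. A preference for short coding sequences was predicted to raise ribosomal protein genes, which had a median of -0.25. That list lay below all random lists, so a fall of its own could mask such a preference. Coding lengths were not used, so the test cannot decide. An effect of the treatment, and chance between single tables, stay open and untested.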

How the results depend on the processing

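The use of deposited values, of coding bins or parts of them and of covered bins was chosen after seeing the data; the other alternatives were planned. For CRISPR against parental, 2.40% of compared genes were past 2-fold, which became 0.835% with a level minimum 4 times higher, 7.37% with none, 3.41% with all rows of a gene summed, 8.46% and 7.93% from the first and last 100 coding bins, 1.92% among genes with 100 covered bins, and 1.65% with values as deposited (0.629% higher against 1.10%). For AZC + MG132 against parental (3.26%) the values were 1.32% with the higher minimum, 6.74% with none, 4.41% with rows summed, 8.50% and 8.23% from the first and last 100 coding bins, 2.40% with 100 covered bins, and 2.13% with values as deposited (0.569% higher against 0.866%). For CRISPR against AZC + MG132 (6.51%) they were 2.84% with the higher minimum, 11.9% with none, 7.93% with rows summed, 13.8% and 14.2% from the first and last 100 coding bins, 5.30% with 100 covered bins, and 4.90% as deposited. The minimums compare fewer, deeper genes and the parts hold fewer bins by construction; for the others the cause was not tested. A larger pseudocount and other scalings kept each of these within 1.5 times, but in AZC + MG132 against parental the genes higher went from 0.866% to 1.44% without the most abundant 1% of rows in the total. The 5′ shift of AZC + MG132 against parental lay between 0.44 and 0.70 and that of CRISPR against AZC + MG132 between -0.62 and -0.41 under the alternatives run. The shift of CRISPR against parental, 0.06, was 0.0361 with the first 40 coding bins and 0.154 as a ratio of sums. The average profile in the first 20 coding bins was 1.58, 1.61 and 1.73 for parental, CRISPR and AZC + MG132. Over the mean of the coding bins, a different denominator, it was 0.965, 0.991 and 1.14. The median over rows gave 1.87, 0.805 and 2.23, and in the CRISPR table that median lies near its floor. The correlation of the changes was 0.0348 from different coding bins and 0.249 from the same coding bins. Of 60 list percentiles 14 lay outside the central 95%, and 11 with the higher minimum. For genes the naming rule selects, 2995 of 3036 alternative values moved by less than 1.5-fold and 41 by more, and 71 had the other sign, all of genes under 2-fold. A gene under the level minimum in coding bins alone, such as KRT10, has no such value in this count. Level minimums and covered bins leave a gene's ratio unchanged, and a scaling moves all ratios by the same amount. Many of the 3036 values could therefore hardly move, so their count is no measure of robustness. Depth counts bases, so it sets no counting interval. No paired analysis was possible because each condition has 1 table.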

Other observations

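The genes with upstream reading frames and the glial list below were tested after values of some members were seen. Depth in the 5′ UTR of ATF4 was 301.5% of coding depth in the parental table, 344.2% in the CRISPR table and 48.1% in the treated cells. For DDIT3, which also has an upstream reading frame, the percentages were 257.1, 145.6 and 81.6, for ATF5 167.5, 216.5 and 88.7, for IFRD1 64.4, 95.2 and 30.95, and for PPP1R15A 62.1, 94.1 and 46.5. PPP1R15B went the other way, at 42.04, 32.3 and 51.1. Coding depth here is all depth in coding bins, whatever the reading frame. Some percentages rest on little coding depth and are uncertain. PPP1R15A had a coding depth of 1648 in the parental and 844 in the CRISPR table, and DDIT3 898 in the parental table. The level minimum over all bins was 3187 in the parental and 3697 in the CRISPR table. Over all genes the median percentage was higher in the treated cells, at 11.6 against 5.88.

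Genes listed for the parental line and absent from the CRISPR table were led by FBN1, the fibrillin of the matrix, at 46.4 in the parental and 45.3 in the AZC + MG132 table. PTK7 stood at 27.2 in the parental table with no CRISPR row.

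Because genes known from glia, CRYAB and CLU among them, were among the lowest in the edited line, although BCAS1, known from oligodendrocytes, was among the highest (2.61), a hypothesis was that genes of the glial lineage, related to melanocytes through the neural crest, are lower together. The values of CDH19 and ITGB4 had been seen before the list was written, so the test leaves them out. The other 18 genes had a median log2 ratio of -0.16, at percentile 2.64 of random lists, which is inside the central 95%, with 11 below 0 and APOD at -1.63 past 2-fold. With CDH19 (-1.14) and ITGB4 (-1.05) included, the 20 genes had a median of -0.21 at percentile 0.56, a result that rests on genes already known to be lower. The abundant CNP and SOX10 were at -0.04 and -0.17, MATN2 was at 0.92 and MBP at 0.63, and 4 of the genes also stand in the melanocyte or mesenchymal list. The test leaves the hypothesis open.

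Because PABPC1, TPT1 and RPL12 were among the lowest in the treated cells, a second hypothesis was that messengers with a 5′ terminal oligopyrimidine tract other than ribosomal proteins are lower together. The 25 compared, without PABPC1 and TPT1, had a median of -0.11, at percentile 17.985, with 14 below 0 and 1 past 2-fold (CCNG1 at -1.31), and 20 of them also stand in another list. EEF1A1 was at -0.11, EEF1G at -0.78 and EIF4A2 at 0.87. The test left the question open.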
